A study of Homo sapiens with 9 samples.

How the data were processed

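RNA was measured in 9 libraries, 3 for each of 3 untreated subclones of the SK-MEL-5 melanoma line. Per the labels, total RNA was extracted with Trizol and libraries followed standard Illumina methods. The authors deposited a table of raw counts of 60675 Ensembl genes in the 9 libraries. Per the submitters' processing notes, HISAT2, featureCounts and GRCh38 were used. Their versions, the annotation release, the strand setting and the treatment of reads with several matches are not given in the sources used here. These can change the counts of overlapping genes, antisense genes, pseudogenes and near-identical copies. Gene names, positions and biotypes were taken from GENCODE 29 on GRCh38, which held 57055 of the IDs. The other 3620 had no name there, so the counting used another release, and 138 of them were among the genes tested.

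Libraries were assigned to clones and replicate numbers by their labels. Total counts ran from 30224066 to 39454087 per library, at which 3 counts in a library correspond to between 0.0760 and 0.0993 CPM. Intervals of count ratios and floors cover counting error only. Libraries of a clone differed by more than sampling noise, with a chi-square per degree of freedom of 2.56 to 11.7, against 62.4 to 197 between clones, so none was counted as a repeat deposit. SC10 replicate 3 stood apart from SC10 replicates 1 and 2 (10.6 and 11.7, against 2.56 between those), and its score on the third principal component was 27.4, against -12.7 and -15.4.

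Genes were kept with edgeR's filterByExpr, leaving 18009, of which 13591 were protein-coding. A further 24415 had no count in any library and 18251 fell below the filter, with at most 0.0893% of a library's counts. Counts were scaled by TMM and fitted over all 9 libraries with edgeR 4.0.16 in R 4.3.3 (robust quasi-likelihood), with the Benjamini-Hochberg threshold at 0.05. Each pair of clones was tested, as were the 3 clones together. CPM values are TMM-scaled. Standard errors were derived from the fitted log2 change and its F statistic. Where a clone held only a few counts, such a standard error is too small. The ± of log2 changes from near 0 CPM in a clone therefore understates their error. For a gene with 0 counts in a clone, a fold was bounded with 3 counts over the clone's libraries, and for 1 to 3 counts the count ratio is given with an exact 95% interval.

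Before the data were examined, 34 gene lists were written. The 32 with at least 5 tested members were tested with camera in limma 3.58.1 on voom values, with a preset correlation of 0.01. The calls hold for 0 lists with an estimated correlation. The fry test, which asks whether a list's genes move on balance in a direction and not whether they differ from other genes, was run beside it. Camera's calls were read as descriptions of these 9 libraries.

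The rule for named genes was also set before the data were examined. It took, among genes past the threshold whose libraries did not overlap and whose mean reached 5 CPM in the higher clone, the 8 with the largest log2 change in each direction. Symbols without a proper name and pseudogenes were passed over. It added up to 4 members of each described list with the largest changes past the threshold, and 8 standing melanoma genes. A few genes that the rule takes are not reported here.

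Alternatives were other scalings, other filters on low counts, DESeq2 1.42.0, limma-voom, a test against a 1.5-fold change, a fit of each pair alone, a non-robust fit, replicate number as a block and leaving out each library in turn. Scaling lists by total counts and leaving out mitochondrially encoded genes were added after seeing the data. On simulated counts, 50 genes were changed by each of 1.25-, 1.5-, 2- and 4-fold per comparison, far fewer than differed in the data. The shares found and false depend on that number, so they are not the error rates of the reported calls. For SC07 against SC01, 82% of genes changed by 2-fold and 52% of those changed by 1.25-fold were found among 17544 tested, and 7.74% of calls were false. The values for SC10 against SC07 were 84%, 46% and 8.70% among 17514 genes. Those for SC10 against SC01 were 76%, 48% and 4.03% among 17539 genes. The false share lay above the nominal 5% in SC07 against SC01 (12 of 155 calls) and SC10 against SC07 (14 of 161). Each comparison had a single simulated data set, so counting error cannot be told apart from a true excess. Shares found are of all 50 changed genes, including any that the filter removed.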

Results

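Gene expression was measured by RNA sequencing in 3 subclones of SK-MEL-5, an established human melanoma cell line that carries a mutated BRAF gene. Each subclone, named SC01, SC07 or SC10, had been grown out from a single cell without drug. Per the labels, the 3 clones were picked by how they first responded to PLX-4720, an inhibitor of BRAF, and the labels do not say which clone responded in which way. All 9 libraries came from untreated cells, 3 for each clone. The comparisons therefore addressed how the untreated clones differed from each other. The deposited counts summed to between 30224066 and 39454087 per library. The labels do not say whether the 3 libraries of a clone came from separate cultures, so the p-values measure only the spread between these libraries, which may be technical. Clone and any batch of culture or extraction cannot be told apart in this design.

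The 3 clones differed widely in expression without drug. Of 18009 genes tested, 13741 (76.3%) differed among the clones at an adjusted p under 0.05 in edgeR's quasi-likelihood test. The first principal component held 63.9% of the variance and set SC01 apart from SC07 and SC10. The second held 21.9% and separated SC07 from SC10. The common biological coefficient of variation among libraries of a clone was 0.0523.

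**Figure D1:**
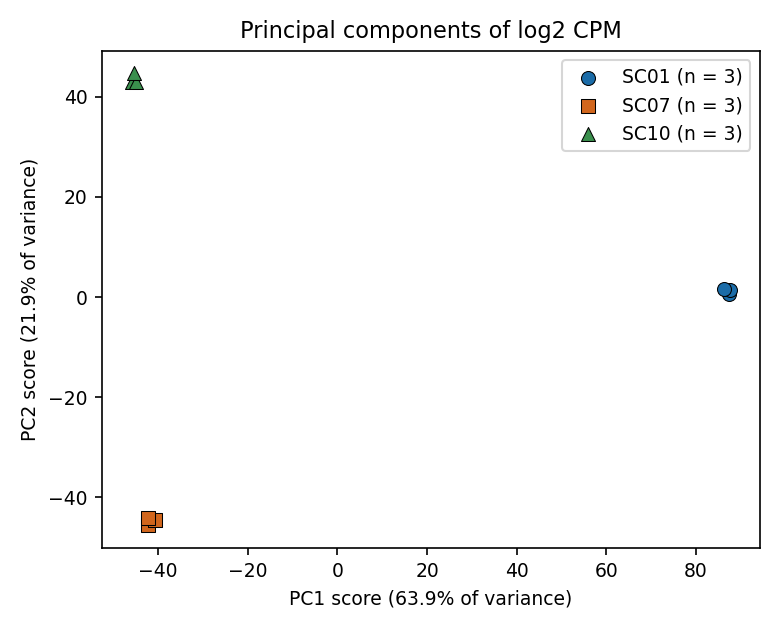
Scores of the 9 libraries on the first and second principal components of log2 CPM, the library-scaled counts, with 3 points per clone. SC01 lies apart along the first component (63.9% of variance) and SC07 and SC10 part along the second (21.9%).

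Several standard melanoma genes were measured in each clone whatever their result. MITF, the transcription factor that governs the melanocyte lineage, stood at 450 ± 1.9 CPM in SC01, 499 ± 13 in SC07 and 550 ± 20 in SC10 (mean ± SD, n = 3 here and below). Its log2 change against SC01 was 0.15 ± 0.041 (SE) in SC07 and 0.29 ± 0.041 in SC10. EGFR, a growth factor receptor, was lower in SC07 (10.5 ± 0.19 CPM) and SC10 (12.2 ± 1.9 CPM) than in SC01 (32.1 ± 0.59 CPM). NOX5, a calcium-regulated NADPH oxidase, stood at 2.90 ± 0.67 CPM in SC01, 5.68 ± 0.80 in SC07 and 78.3 ± 4.6 in SC10. BRAF measured 42.1 ± 3.0, 58.2 ± 3.3 and 61.4 ± 6.3 CPM in the same order, and the last pair did not differ past the threshold (adjusted p = 0.364, edgeR). KDM5B, a histone demethylase, measured 79.6 ± 2.8, 97.9 ± 3.6 and 107 ± 6.8 CPM. Between SC10 and SC07, the changes of EGFR (0.22, adjusted p = 0.0444, edgeR) and KDM5B (0.12, adjusted p = 0.0458) lay near the threshold and were lost with DESeq2 and without SC10 replicate 1 or 2. NGFR, a receptor of neural crest cells, measured 0.743 ± 0.081, 0.560 ± 0.17 and 1.75 ± 0.26 CPM, and AXL, a receptor tyrosine kinase, had clone means between 0.224 and 0.375 CPM with no difference past the threshold. SOX10 was listed with 0 counts in all 9 libraries and was not tested.

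**Figure D2:**
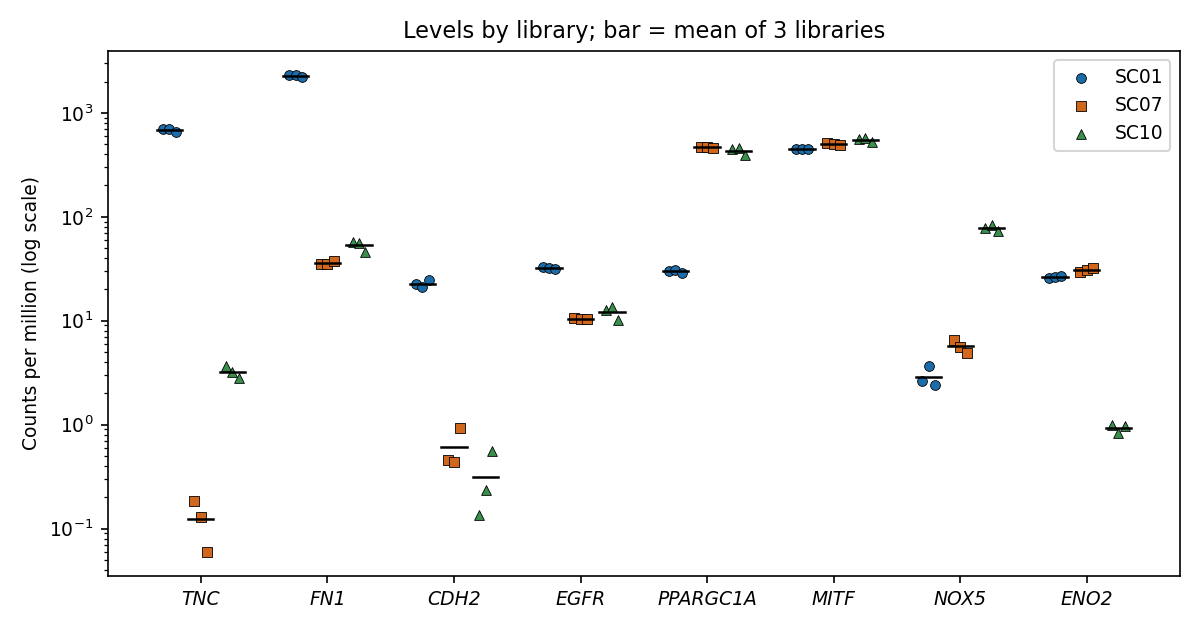
CPM (log axis) of 8 genes in each library, with a bar at the mean of the 3 libraries of a clone. The clone means of TNC ran from 685 CPM in SC01 to 0.124 in SC07, and those of NOX5 from 2.90 CPM in SC01 to 78.3 in SC10, while the clone means of MITF lay between 450 and 550 CPM.

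The comparison of SC07 with SC01 showed large differences in single genes of the matrix, of adhesion and of mitochondria. TNC, which encodes the matrix protein tenascin C, fell from 685 ± 26 CPM in SC01 to 0.124 ± 0.062 in SC07. FN1, encoding fibronectin, fell from 2286 ± 60 to 36.0 ± 1.4 CPM, and CDH2, encoding N-cadherin, from 22.6 ± 1.7 to 0.607 ± 0.28 CPM. PPARGC1A, a coactivator that drives mitochondrial genes, rose from 30.2 ± 1.0 to 468 ± 6.4 CPM. Of 48 nuclear genes of oxidative phosphorylation, 46 were higher in SC07 and 0 were lower (camera adjusted p = 2.7e-17, and adjusted p = 0.345 with an estimated correlation).

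Among the largest gains in SC07 was KCNG4, a potassium channel subunit (GRCh38 chromosome 16, 84218667 to 84239750), at 44.1 ± 1.3 CPM against 0.0809 ± 0.091 in SC01, a log2 change of 9.06 ± 0.18 (SE). KCNG4 had only a few counts in SC01, so its standard error is too small, as for other genes near 0 CPM in a clone. FUT3, a fucosyltransferase, gained 7.41 ± 0.25 on the log2 scale, CDH7, a cadherin, 7.18 ± 0.25, MUC19, a mucin, 7.01 ± 0.23, and TFCP2L1, a transcription factor, 6.87 ± 0.23. C17orf77 gained 7.12 ± 0.15, but GENCODE 29 annotates it as antisense and the strand setting of the counting is not stated. CTNND2, encoding delta-catenin, and ATP2B2, a plasma membrane calcium pump, each had 3 counts over the SC01 libraries. Their count ratios were 261 (95% counting interval 88.8 to 1266) and 226 (76.9 to 1098).

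Among the largest losses, PXDN, encoding the matrix peroxidase peroxidasin (chromosome 2, 1631887 to 1744852), had 0 counts in SC07 and 67.2 ± 2.7 CPM in SC01. It was at least 2356-fold lower, taking 3 counts over the clone as the floor. FLT1, a receptor of vascular endothelial growth factor, was at least 238-fold lower on the same terms. TNC (chromosome 9, 115019578 to 115118257) changed by -12.39 ± 0.11 on the log2 scale, with an adjusted p of 6.09e-33 (edgeR). Its SC07 libraries lay between 0.0597 and 0.183 CPM, only a few counts each, so that standard error is too small. CADM3, a cell adhesion molecule, changed by -9.38 ± 0.13, though 36.8% of its exon bases overlap another gene, and EFEMP1, a matrix glycoprotein, by -8.77 ± 0.14. PCSK1, DOK5 and ARHGAP6 had 3, 2 and 2 counts over SC07 and count ratios of 678, 473 and 365 in favour of SC01, with 95% intervals from 232 to 3289, 131 to 3912 and 101 to 3022.

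Of 30 collagen, laminin and integrin genes, 20 were lower in SC07 and 7 higher. COL4A2 and COL4A1, chains of basement membrane collagen, changed by -5.72 ± 0.11 and -5.30 ± 0.15, while ITGA7, a laminin-binding integrin chain, gained 3.89 ± 0.05. Of 21 epithelial-mesenchymal and cadherin genes, 14 were lower and 4 higher, among them TGFBI (-6.49 ± 0.14) and FN1 (-5.99 ± 0.07). The camera test gave adjusted p = 0.000912 and 0.000773 for these lists with the preset correlation, against adjusted p = 0.345 and 0.109 with an estimated correlation. The neural crest-like list had 13 of 18 members lower and 1 higher, with CADM1 at -3.85 ± 0.06, GDNF at -3.08 ± 0.14 and TFAP2A at -1.59 ± 0.04 (camera adjusted p = 9.98e-05, and adjusted p = 0.104 with an estimated correlation). The AXL-high list had 13 of 22 lower and 3 higher, with JUN at -2.85 ± 0.10 (camera adjusted p = 0.00561, and adjusted p = 0.114 with an estimated correlation).

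Of 20 NF-kB targets and cytokines, 12 were lower in SC07 and 5 higher, including the chemokines CXCL1 (57.7 ± 1.7 to 1.11 ± 0.13 CPM) and CCL2 (6.34 ± 0.79 to 0.0779 ± 0.065 CPM). Of 24 p53 targets and cell-cycle inhibitors, 16 were lower and 6 higher. CDKN1A, encoding the cell-cycle inhibitor p21, changed by -1.80 ± 0.05, and GDF15, a stress-induced cytokine, by 1.37 ± 0.05. Of 22 immediate-early genes, 14 were lower and 4 higher, with RHOB at -2.19 ± 0.07 and DUSP1, a phosphatase of MAP kinases, at 2.43 ± 0.08. The camera adjusted p was 0.022 for the NF-kB list, 0.0032 for the p53 list and 0.0027 for the immediate-early list, against adjusted p = 0.313, 0.220 and 0.220 with an estimated correlation. Markers of other cell types moved in both directions in the same libraries. Of 6 fibroblast markers 2 were higher and 3 lower (camera adjusted p = 0.966, and adjusted p = 0.967 with an estimated correlation), with a median of -0.36 and a mean of 0.10 on the log2 scale. LUM, a matrix proteoglycan, measured 462 ± 34 CPM in SC07 and 131 ± 2.2 in SC01, and FBLN1, another matrix protein, 9.59 ± 0.21 and 30.5 ± 0.89. Of 7 keratinocyte markers 3 were higher and 1 lower, or 3 and 2 with library totals as the only scaling (camera adjusted p = 0.633, and adjusted p = 0.662 with an estimated correlation). Of 3 immune markers, too few for the list test, 2 were higher, with PTPRC at 3.12 ± 0.50 CPM in SC07 and 0.173 ± 0.15 in SC01.

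Besides the 46 nuclear oxidative phosphorylation genes, all 13 mitochondrially encoded mRNAs were higher in SC07, by a median of 0.58 on the log2 scale. ATP5MC3, a subunit of ATP synthase, gained 1.43 ± 0.05, and MT-ND1, a subunit of complex I, gained 1.06 ± 0.04. The share of counts in mitochondrial mRNAs was 8.67% ± 0.25 in SC07 and 6.42% ± 0.058 in SC01. Signs of RNA and library quality moved in the same libraries. Mitochondrial rRNA took 0.976% to 1.03% of counts in the SC07 libraries and 0.521% to 0.551% in those of SC01. Of 7 abundant nuclear and small structured RNAs 3 were higher and 2 lower (camera adjusted p = 0.633, and adjusted p = 0.685 with an estimated correlation). The list of replication-dependent histone genes, written for mRNAs without a poly(A) tail, had 10 tested members. Of these, 4 were higher and 3 lower, or 3 and 4 with library totals as the only scaling (camera adjusted p = 0.966, and adjusted p = 0.967 with an estimated correlation). Whether their counts came from mRNAs without a tail was not tested. For the histone genes the median of -0.06 and the mean of -0.22 lay opposite to the direction of the camera test. Of 49 ribosomal protein genes, 42 were lower and 0 higher, with a median of -0.37 and RPS12 at -1.69 ± 0.06. How reads shared with ribosomal protein pseudogenes were counted is not stated. The camera adjusted p was 2.7e-17, 7.3e-07 and 6.2e-10 for the nuclear oxidative phosphorylation, mitochondrially encoded and ribosomal protein lists, against adjusted p = 0.345, 0.109 and 0.523 with an estimated correlation. Of 28 glycolysis genes, 20 were higher and 7 lower, with PFKFB2 at 1.72 ± 0.05 and HK2, a hexokinase, at -1.88 ± 0.05 (camera adjusted p = 0.0053, and adjusted p = 0.396 with an estimated correlation).

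Of 29 calcium transport genes, 19 were higher in SC07 and 2 lower, among them SLC8A1, a sodium-calcium exchanger (4.74 ± 0.27). Their camera adjusted p was 0.00077, and adjusted p = 0.305 with an estimated correlation. The pigmentation list had 14 of 24 members higher and 7 lower (camera adjusted p = 0.041, and adjusted p = 0.396 with an estimated correlation). SLC45A2, a melanosome transporter, gained 1.95 ± 0.05, while SLC24A5, another one, changed by -2.05 ± 0.07, with 32.9% of its exon bases overlapped by another gene. Of 24 cholesterol synthesis genes 15 were lower and 5 higher, and of 28 genes of the unfolded protein and integrated stress response 17 were higher and 8 lower (camera adjusted p = 0.049 and 0.048, and adjusted p = 0.396 and 0.602 with an estimated correlation). The cholesterol synthesis list lost its call without SC01 replicate 2 or 3 or SC07 replicate 2 (adjusted p = 0.0503, 0.0581 and 0.0697) and with a minimum of 1 CPM in 3 libraries (0.0523). The unfolded protein and integrated stress response list, with VLDLR at 1.66 ± 0.06, lost it without SC01 replicate 1 or SC07 replicate 3 (0.0529 and 0.0511), with that minimum (0.0733) and with total counts (0.0677).

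In total, 11162 of 18009 genes differed between SC07 and SC01 at an adjusted p under 0.05, 5675 higher and 5487 lower in SC07. Changes of at least 2-fold numbered 1647 higher and 1563 lower. With library totals as the only scaling, the split was 4666 higher and 6841 lower, and the median of all genes lay at -0.12 on the log2 scale. Against a minimum change of 1.5-fold, 3703 genes passed. The libraries of the 2 clones did not overlap for 67.4% of genes, where chance gives 10%. Among the lists described, counts adjusted over the list alone were 14 lower in the AXL-high list, 14 in the neural crest-like list, 21 in the collagen list, 14 in the NF-kB list and 4 in the histone list, and equal to the counts over all genes tested in the other lists.

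The comparison of SC10 with SC01 used the same 3 SC01 libraries. NOX5 rose by 4.76 ± 0.11 on the log2 scale (adjusted p = 1.21e-19, edgeR), and CYBA, a subunit of other NADPH oxidases, rose by 5.42 ± 0.14. Of 7 NADPH oxidase genes and regulators, 3 were higher and 2 lower (camera adjusted p = 0.448, and adjusted p = 0.563 with an estimated correlation). TNC fell from 685 ± 26 to 3.24 ± 0.44 CPM and FN1 from 2286 ± 60 to 52.9 ± 6.4 CPM. PPARGC1A rose from 30.2 ± 1.0 to 433 ± 35 CPM. ENO2, the neuronal enolase of glycolysis, fell from 26.3 ± 0.52 to 0.929 ± 0.085 CPM.

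Among the largest gains in SC10 was EPHA7, an ephrin receptor (chromosome 6, 93240020 to 93419547), at 27.6 ± 1.8 CPM against 0.0499 ± 0.086 in SC01, a log2 change of 9.03 ± 0.24. EPHA7 had only a few counts in SC01, so that standard error is too small. KCNG4 gained 8.54 ± 0.18, PLEKHA2, a phosphoinositide-binding adaptor, 7.39 ± 0.31, TFCP2L1 7.05 ± 0.23 and SLIT1, an axon guidance ligand, 6.97 ± 0.17. ATP2B2, RAB37 and CTNND2 each had 3 counts over SC01, with count ratios of 680, 220 and 199 (95% intervals 232 to 3298, 74.9 to 1069 and 67.7 to 967). Among the largest losses, ARHGAP6 had 0 counts in SC10 and was at least 242-fold lower. EFEMP1 changed by -8.54 ± 0.14, PCSK1, a prohormone convertase, by -8.55 ± 0.21, PXDN by -8.36 ± 0.13, GRIK3, a glutamate receptor subunit, by -8.13 ± 0.22, TNC by -7.72 ± 0.07 and DOK5 by -7.45 ± 0.30. FLT1 had 3 counts over SC10, and the count ratio in favour of SC01 was 236 (80.4 to 1147).

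Of 48 nuclear oxidative phosphorylation genes, 42 were higher in SC10 and 1 lower, with a median of 0.68. NDUFS1 of complex I gained 1.29 ± 0.04 and UQCRB of complex III 1.33 ± 0.06. All 13 mitochondrially encoded mRNAs were higher, with a median of 0.69, and their share of counts was 9.69% ± 0.24. In the same libraries mitochondrial rRNA took 1.03% to 1.09% of counts, against 0.521% to 0.551% in those of SC01. Of the 7 abundant nuclear and small structured RNAs 3 were higher and 1 lower, with NEAT1 at 560 ± 36 CPM in SC10 and 258 ± 20 in SC01, and of the 10 histone genes 1 was higher and 4 lower (camera adjusted p = 0.292 and 0.448, and adjusted p = 0.551 and 0.571 with an estimated correlation). Of 49 ribosomal protein genes, 42 were lower and 2 higher, with a median of -0.39 and RPLP0 at -0.72 ± 0.05. The camera adjusted p was 4.6e-14, 8.3e-08 and 2.5e-09 for the nuclear oxidative phosphorylation, mitochondrially encoded and ribosomal protein lists, against adjusted p = 0.463, 0.119 and 0.551 with an estimated correlation. Calcium transport genes were higher in 19 of 29 and lower in 4, with SLC8A1 at 6.07 ± 0.24 and CACNA2D2, a calcium channel subunit, at 3.12 ± 0.16 (camera adjusted p = 0.0092, and adjusted p = 0.443 with an estimated correlation). Genes of the unfolded protein and integrated stress response were higher in 17 of 28 and lower in 8, with MANF at 1.40 ± 0.05 (camera adjusted p = 0.025, and adjusted p = 0.551 with an estimated correlation). The pigmentation list had 16 of 24 higher and 7 lower, with SLC45A2 at 1.83 ± 0.05 and TYRP1 at -1.77 ± 0.04 (camera adjusted p = 0.045, and adjusted p = 0.498 with an estimated correlation).

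The neural crest-like list had 14 of 18 members lower in SC10 and 3 higher, with CADM1 at -3.08 ± 0.06 and SOX9 at -2.96 ± 0.29 (camera adjusted p = 0.0010, and adjusted p = 0.119 with an estimated correlation). The p53 list had 16 of 24 lower and 5 higher, with CDKN1A at -1.87 ± 0.05 (camera adjusted p = 0.0052, and adjusted p = 0.321 with an estimated correlation). Of the fibroblast markers, 2 of 6 were higher and 1 lower, or 2 and 3 with library totals as the only scaling (camera adjusted p = 0.593, and adjusted p = 0.647 with an estimated correlation), with LUM at 350 ± 18 CPM in SC10. Of the keratinocyte markers, 1 of 7 was higher and 4 lower (camera adjusted p = 0.472, and adjusted p = 0.571 with an estimated correlation), and of the 3 immune markers 1 was higher and 0 lower. The collagen, laminin and integrin list had 18 of 30 lower and 10 higher, with COL4A2 at -2.83 ± 0.08 and ITGA7 at 3.41 ± 0.05 (camera adjusted p = 0.030, and adjusted p = 0.546 with an estimated correlation). The epithelial-mesenchymal and cadherin list had 13 of 21 lower and 5 higher, with CDH2 at -6.19 ± 0.23 (camera adjusted p = 0.043, and adjusted p = 0.337 with an estimated correlation). The AXL-high list had 11 of 22 lower and 5 higher, with WNT5A, a Wnt ligand, at -2.88 ± 0.23, and the NF-kB list had 12 of 20 lower and 3 higher, with CXCL1 at -3.06 ± 0.07. Both lists had camera adjusted p = 0.045, and adjusted p = 0.321 and 0.443 with an estimated correlation. The list of the undifferentiated, AXL-high melanoma state lost its call without SC10 replicate 1 or 3 (adjusted p = 0.0502 and 0.0576), and that of NF-kB targets and inflammatory cytokines without SC10 replicate 1 (0.0539). With library totals as the only scaling, these lists (0.0909 and 0.0904) and that of epithelial-mesenchymal and cadherin genes (0.0647) no longer passed.

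In total, 11864 genes differed between SC10 and SC01, 6028 higher and 5836 lower in SC10, and 2022 and 1495 of these changed by at least 2-fold. Against a minimum change of 1.5-fold, 4192 genes passed. The libraries of the 2 clones did not overlap for 69.1% of genes, where chance gives 10%. With library totals as the only scaling, the median of all genes lay at -0.12 and the share of called genes that were higher was 41.6% rather than 50.8%. Adjusted over the list alone, 3 histone genes were lower, and the counts in the other lists described were equal to those over all genes tested.

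**Figure D3:**
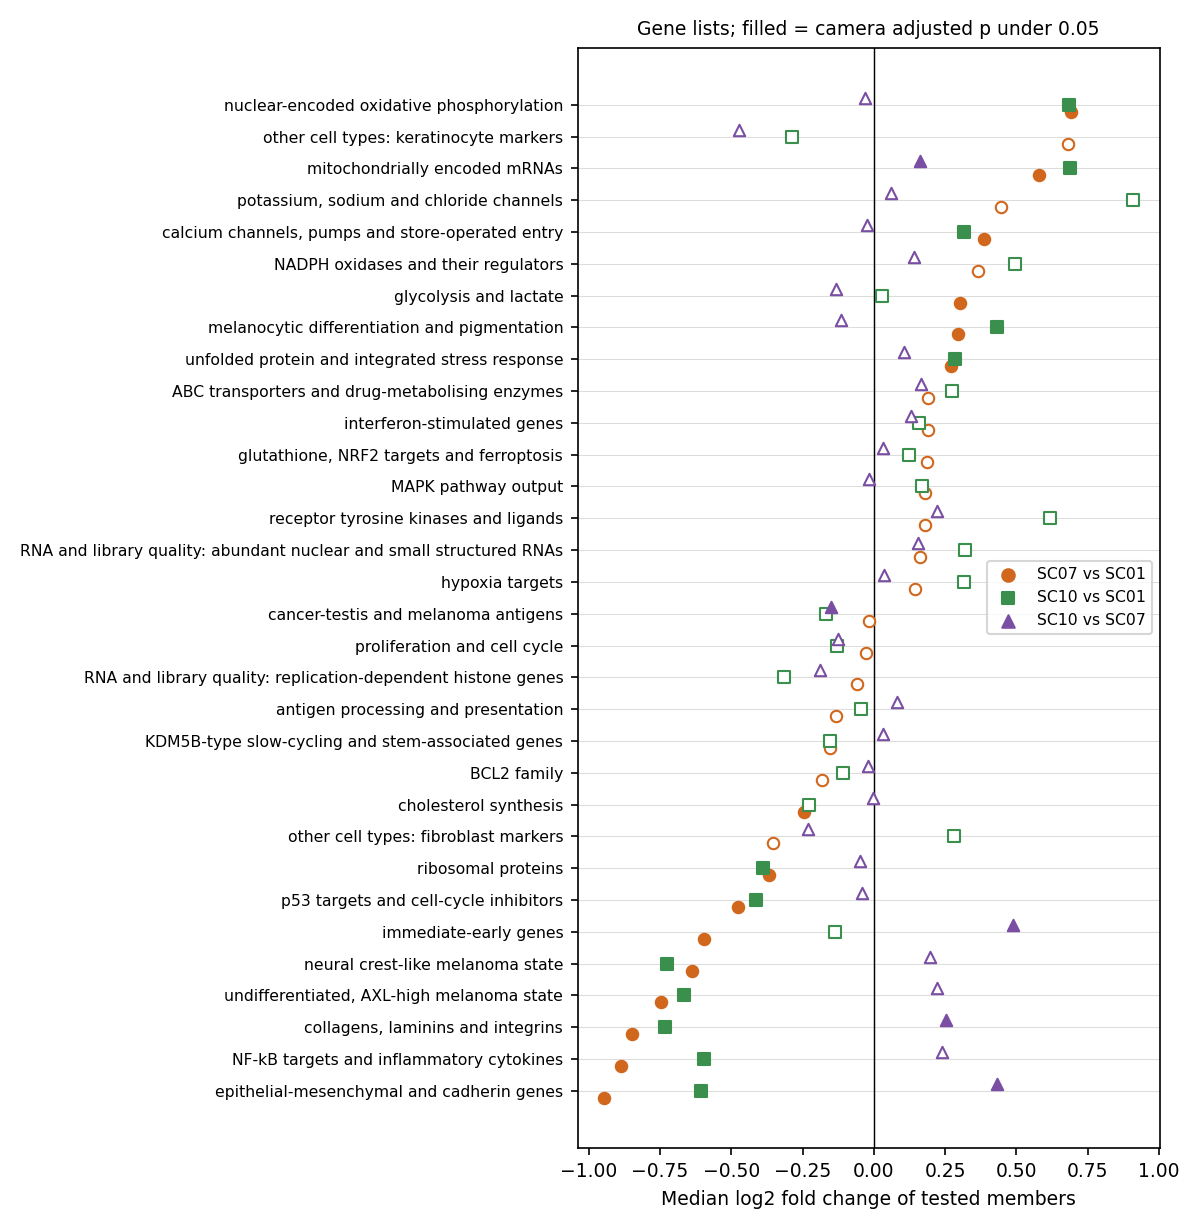
Median log2 fold change of the tested members of 32 gene lists in the 3 comparisons. Filled symbols mark a camera adjusted p under 0.05 with the preset correlation, and 0 lists pass in any comparison with an estimated correlation. Nuclear oxidative phosphorylation lies at 0.69 and 0.68 in SC07 and SC10 against SC01 and at -0.03 in SC10 against SC07.

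SC10 and SC07 differed in fewer genes than either did from SC01. NOX5 was higher in SC10 by 3.79 ± 0.09 on the log2 scale (adjusted p = 4.66e-18, edgeR). ENO2 was lower in SC10 by -5.04 ± 0.10. VIM, encoding the filament protein vimentin, stood at 555 ± 38 CPM in SC10 and 202 ± 5.1 in SC07. The melanosome gene PMEL was lower in SC10, with a log2 change of -0.83 ± 0.05, as was DCT, a pigment enzyme, with -0.87 ± 0.04. Of 24 pigmentation genes, 8 were higher and 12 lower (13 adjusted over the list alone), and the list did not pass (camera adjusted p = 0.312, and adjusted p = 0.706 with an estimated correlation).

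Among the largest gains in SC10 over SC07, EPHA7 gained 8.28 ± 0.22, BARX2, a homeobox factor (chromosome 11, 129375940 to 129452279), 8.22 ± 0.23, JCAD, a junction protein, 6.24 ± 0.29, NRCAM, a neuronal adhesion molecule, 5.86 ± 0.09, CACNG7, a calcium channel subunit, 4.77 ± 0.14, and BAIAP2L2 4.68 ± 0.16. ITGB3, an integrin chain, gained 4.43 ± 0.13, but 51.6% of its exon bases overlap a gene on the same strand. PLEKHA2 had 3 counts over SC07 and a count ratio of 311 (95% interval 106 to 1512). Among the largest losses, RXFP1, the relaxin receptor (chromosome 4, 158315311 to 158653372), had 0 counts in SC10 and was at least 319-fold lower. MGAM2, related to maltase-glucoamylase, changed by -7.31 ± 0.23, PTPRR, a tyrosine phosphatase, by -4.53 ± 0.23, GLRB, a glycine receptor subunit, by -4.40 ± 0.21, PRSS33, a serine protease, by -4.27 ± 0.23, RLBP1, a retinaldehyde-binding protein, by -4.07 ± 0.07 and ITGA10, a collagen-binding integrin chain, by -3.82 ± 0.06.

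Of 30 collagen, laminin and integrin genes, 18 were higher in SC10 than in SC07 and 4 lower, including COL5A1 at 3.03 ± 0.14. Of 21 epithelial-mesenchymal and cadherin genes, 10 were higher and 3 lower, including TGFBI at 2.29 ± 0.19. Of 22 immediate-early genes, 12 were higher and 4 lower, including EGR1, a growth factor-induced transcription factor, at 1.11 ± 0.14. Of 13 mitochondrially encoded mRNAs, 8 were higher and 0 lower, including MT-ATP6 at 0.33 ± 0.04. Of the 7 abundant nuclear and small structured RNAs 4 were higher and 0 lower, or 2 and 0 with library totals as the only scaling, and of the 10 histone genes 1 was higher and 3 lower (both camera adjusted p = 0.339, and adjusted p = 0.706 with an estimated correlation). Of 18 cancer-testis antigens, 9 were lower and 1 higher, including MAGEA1 at -1.42 ± 0.14 and GAGE1 at -2.89 ± 0.08, a gene with near-identical copies whose counts are uncertain. The camera adjusted p was 0.032 for the collagen, immediate-early and mitochondrial lists and 0.042 for the other 2, against adjusted p = 0.706 for each with an estimated correlation. Adjusted over the list alone, 2 cancer-testis genes were higher, and the counts in the lists named beside them were equal. With a minimum of 1 CPM in 3 libraries, and without SC10 replicate 2, 0 lists passed. Without SC07 replicate 3, 3 lists passed, as the epithelial-mesenchymal and cadherin genes and the cancer-testis and melanoma antigens each moved to adjusted p = 0.0516. The first of these also lost its call without SC07 replicate 1 (0.0689), and the second without SC10 replicate 1 (0.0523).

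In total, 8620 genes differed between SC10 and SC07, 4475 higher and 4145 lower in SC10, and 1051 and 502 of these changed by at least 2-fold. Against a minimum change of 1.5-fold, 1444 genes passed. The libraries did not overlap for 53.4% of genes, where chance gives 10%. Markers of other cell types moved in both directions. Of 7 keratinocyte markers 2 were higher in SC10 and 4 lower. Of 6 fibroblast markers 2 were higher, both by at least 2-fold, and 3 lower, 1 of them by at least 2-fold. The camera adjusted p was 0.479 and 0.942 for these lists, and adjusted p = 0.706 and 0.970 with an estimated correlation. The fibroblast markers had a median of -0.23 and a mean of 0.11 on the log2 scale. Of 3 immune markers 0 were higher and 2 lower. KRT14, a keratin of keratinocytes, measured 0.0197 ± 0.017 CPM in SC10 and 1.23 ± 0.43 in SC07, and PTPRC, a marker of immune cells, 0.735 ± 0.14 and 3.12 ± 0.50.

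Fold changes also differed by chromosome. Genes on chromosome 6 had a median log2 change of -0.40 in SC07 and -0.42 in SC10 against SC01, and genes on chromosome 4 had medians of 0.38 and 0.32. Genes on chromosome 8 had medians of 0.26 and 0.43. Between SC10 and SC07, the medians were -0.34 on chromosome 12, 0.31 on chromosome 10 and 0.28 on chromosome 11. The SD of the medians over 23 chromosomes was 0.197, 0.219 and 0.152 in the 3 comparisons, against at most 0.0428, 0.0495 and 0.0328 in 1000 permutations of gene positions (permutation p = 0.001, the smallest they can give). Named genes such as CDKN1A, TFAP2A and RPS12 on chromosome 6 and PPARGC1A on chromosome 4 lie on these chromosomes.

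**Figure D4:**
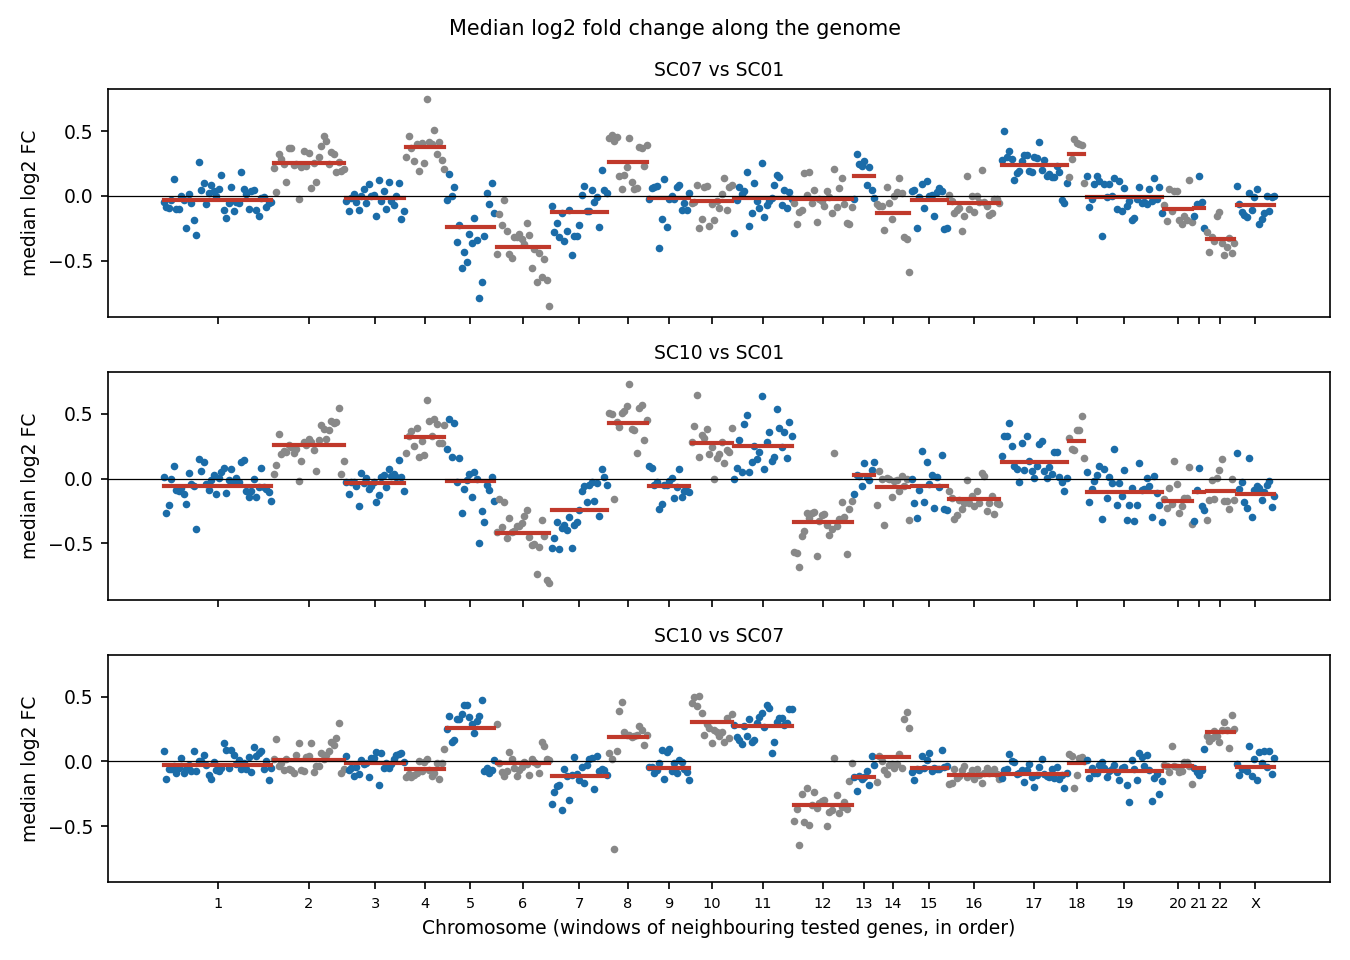
Median log2 fold change in windows of about 40 neighbouring tested genes (points) and over each chromosome (bars), for the 3 comparisons, with chromosomes 1 to X along the axis. Chromosome 6 lies at -0.40 and -0.42 in SC07 and SC10 against SC01, and chromosome 12 at -0.34 in SC10 against SC07.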

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

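Total counts for the lists and the fits without mitochondrially encoded genes were chosen after seeing the data. The counts of genes and the 8608 values of named genes under alternatives were mostly stable. Of those values, over 435 pairs of gene and comparison, 8392 kept their direction and side of the threshold, 215 no longer passed, 1 newly passed and 0 reversed. Of the 215, 90 came from the test against a 1.5-fold change. Most named genes had been picked for large changes past the threshold in these data, so their stability says little about other genes. Leaving out 1 library gave 10454 to 11793 genes for SC07 against SC01, 11299 to 12026 for SC10 against SC01, 7627 to 8548 for SC10 against SC07 and 13321 to 13904 among the 3 clones. DESeq2 called 10696, 11429, 8079 and 13301. Testing against a 1.5-fold change, a stricter hypothesis by construction, called 3703, 4192 and 1444. Replicate numbers did not pair the libraries. Same-numbered libraries deviated together with correlations of -0.020 to 0.043, and a replicate block called 11249, 11926, 8754 and 13809 genes and 14, 12 and 5 lists, with cholesterol synthesis in SC07 against SC01 at adjusted p = 0.0561. The list calls depended on the test. Camera with the preset correlation called 15, 12 and 5 lists, an estimated correlation called 0, 0 and 0 (6, 4 and 1 at an unadjusted p under 0.05), and fry called 30, 29 and 23. Fry answers a different question. At 3 libraries per clone the estimate is itself uncertain. In SC07 against SC01, the neural crest-like and AXL-high lists had estimated correlations of -0.039 and -0.013, below the preset 0.01. They lost their calls all the same, which argues against correlated genes as the cause for these lists. The other called lists had estimates from 0.014 (epithelial-mesenchymal and cadherin genes) to 0.860 (ribosomal proteins), and the cause of their lost calls was not tested. For SC10 against SC07 a minimum of 1 CPM in 3 libraries called 0 lists, and leaving out 1 library called 0 to 7, with 0 without SC10 replicate 2, 3 without SC07 replicate 3 and 7 without SC10 replicate 3, the library that stood apart. The cause was not tested. The other comparisons gave 14 to 15 and 10 to 12 lists. Without mitochondrially encoded genes 11111, 11820, 8582 and 13680 genes were called, and total counts gave 15, 10 and 5 lists. Depth limits genes near 0.1 CPM, where a clone holds only a few counts.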

Other observations

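Further gene lists held changes in single genes, while the lists as a whole did not pass in camera. MET, the receptor of hepatocyte growth factor, stood at 94.2 ± 1.6 CPM in SC01, 570 ± 2.2 in SC07 and 723 ± 57 in SC10 (mean ± SD, n = 3). SLC7A11, the cystine transporter, measured 3.82 ± 0.069, 54.9 ± 0.69 and 23.4 ± 2.4 CPM in the same order, and ABCB1, a drug efflux pump, measured 0.250 ± 0.19, 6.16 ± 0.20 and 5.37 ± 0.58 CPM. FOSL1, a transcription factor downstream of MAP kinases, was lower in SC07 and SC10 than in SC01, by log2 changes of -1.60 ± 0.06 and -1.08 ± 0.06. SPRY1, a feedback inhibitor of the same pathway, was higher by 1.56 ± 0.05 and 1.88 ± 0.05. Of 24 genes of MAPK pathway output, 12 were higher and 10 lower in SC07 against SC01, and 13 and 7 in SC10 against SC01 (camera adjusted p = 0.486 and 0.292, and adjusted p = 0.662 and 0.563 with an estimated correlation).

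Of 39 genes of proliferation and cell cycle, 12 were higher and 13 lower in SC07 against SC01, 10 and 21 in SC10 against SC01, and 6 and 18 in SC10 against SC07. With total counts as the scaling, the splits were 7 and 19, 6 and 23, and 6 and 18, and the median in SC07 against SC01 moved from -0.03 to -0.14. With TMM scaling, the camera adjusted p was 0.875, 0.161 and 0.0777, and adjusted p = 0.962, 0.563 and 0.706 with an estimated correlation. FOXM1, a transcription factor of dividing cells, measured 142 ± 1.6 CPM in SC01, 136 ± 5.3 in SC07 and 81.2 ± 3.7 in SC10. Of 28 glycolysis genes, 11 were higher and 11 lower in SC10 against SC01, and the median turned from 0.03 to -0.08 with total counts as the scaling.

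Of the tests that follow, the overlap of library medians by chromosome and the level of POLR2F were chosen after the result was seen. The other bounds for the patterns of chromosomes, oxidative phosphorylation and SOX10 were set before those tests, but after the patterns themselves had been seen. In the test of all 3 clones, 1 of 100 splits of the 9 libraries, the real one, called as many as 13741 genes, and the highest other split called 7303. Libraries differed far less within a clone than between clones, so this outcome was largely given beforehand. It shows that the libraries group by clone, and not whether the differences would recur in separate cultures. For each pair, 3 libraries against 3 make 10 splits, too few for a share under 0.05. The real split was 1 of 10 for genes in each pair (11162, 11864 and 8620, highest other 0 each). For lists, 1, 1 and 2 of 10 splits called as many as the real ones (15, 12 and 5, highest other 8, 5 and 7).

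Shifts of expression by chromosome separated the clones, and some covered only part of a chromosome. On chromosome 5 in SC07 against SC01, window medians were -0.79 to -0.17 from 51372736 to 151093577 and -0.13 to 0.17 elsewhere. All windows of chromosome 4 lay between 0.19 and 0.74 in that comparison. Removing a trend on GC content and on the union of a gene's annotated exons as its length left at least 97.5% of the SD of the chromosome medians. This argued against a bias of these 2 measures. The length of the mRNAs themselves was not used. The largest chromosome median between libraries of a clone, 0.0731, was 18.3%, 17.2% and 21.6% of the largest shift in the 3 comparisons. It was taken between single libraries on log2 CPM, while the shifts were fitted log2 changes of 3 libraries against 3. The shares are therefore approximate. The bound of under 20% set beforehand, which named no comparison, was met in the first and second but not in SC10 against SC07. By the later test, 0 of 22 shifts of at least 0.2 had overlapping library medians, an outcome that largely follows from that small maximum. Medians of the lower- and higher-expressed genes of each chromosome correlated across chromosomes at 0.916 or more. Any cause that shifts most genes of a chromosome would give this, so the correlation does not single out gene dosage. Differences in copy number of chromosomes or parts of them may be a candidate explanation, as a hypothesis, since DNA was not measured here. Among called genes placed on chromosomes 1 to 22 and X in GENCODE 29, 2931, 3144 and 1451 differed by at least 2-fold after subtracting the median of neighbouring genes, against 3172, 3465 and 1538 before.

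Of 48 nuclear oxidative phosphorylation mRNAs, 46 were higher and 0 lower in SC07 than in SC01 and 42 and 1 in SC10, and of 49 ribosomal protein mRNAs 0 were higher and 42 lower in SC07 and 2 and 42 in SC10. With an estimated correlation these lists did not pass in camera (adjusted p = 0.345 and 0.463 for the first list, 0.523 and 0.551 for the second). The oxidative phosphorylation median kept at least 100.1% after removing a trend on GC content and length. It kept at least 94.5% after subtracting the median of neighbouring genes and stayed at 0.573 or more under 4 scalings. These values argued against GC content, position and scaling as the whole cause. Length was the union of a gene's annotated exons, with a median of 3045 bases for these genes, and not that of its mRNA. A bias tied to mRNA length or RNA quality was therefore not tested. The median of 78 mitochondrial ribosomal protein genes was 0.27 (95% bootstrap interval over the genes, not over libraries, 0.11 to 0.38) in SC07 and 0.19 (0.04 to 0.30) in SC10, the lower of them, 0.190, lying between the bounds set beforehand, so a wider rise of mitochondrial mRNAs stays open. A difference between the clones could also come from their culture or extraction, which cannot be told apart from the clone here.

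SOX10, a lineage factor of melanocytes, had 0 counts in all 9 libraries. Reads shared with a second gene may have been left uncounted, but in GENCODE 29 only 2.40% of its exon bases lie in another gene, which met the bound of under 50% set beforehand against this. That bound was wrong to rest on GENCODE 29, since 3620 of 60675 IDs are not in it and the annotation used for counting is not given in the sources used here. Of 352 protein-coding genes covered to at least 95%, 60.5% had no count, against 13.1% of 11319 with none covered. Among the 6855 covered to 1 to 50%, where GENCODE 29 places SOX10, 3.47% had no count. The neighbour POLR2F reached at most 54.1% of the lowest of 11 other RNA polymerase II subunits, a value found from the same data that decides nothing, so the 0 counts cannot be told apart from absence of the transcript.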
